A study of Mus musculus with 12 samples.

How the data were processed

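Total RNA was extracted with Trizol and libraries were made from samples with an RNA integrity number over 8.0, per the labels' protocols. The table of all samples holds raw read counts per gene as deposited by the authors, as whole numbers that were not normalized. Reads were aligned with HISAT2 to the mm10 build, per the submitters' processing notes, which name no versions. The counting program, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. The file names genes by symbol, and Pck1 was placed with the RefSeq annotation of GRCm38.p6, the same assembly as mm10.

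The genotype label put 7 libraries in KO and 5 in WT, and replicates were numbered by the order of their accessions. The title of KO replicate 7 starts with KP rather than KO, and the library was kept in KO by its genotype label. Nothing in the labels gives sex, age, batch or pairing, or says that the libraries came from separate animals, so p-values measure the spread between these samples. No pair of libraries within a group agreed within sampling noise (the smallest chi-square per degree of freedom was 80.9). The table has 46095 genes, of which 26342 had any count. Total counts ran from 17462102 to 46747125.

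Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 14666 genes with 99.9% of the counts. They were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling and robust quasi-likelihood F-tests (glmQLFit, glmQLFTest) of KO against WT over the 12 libraries, without covariates, and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.492. The standard error of a log2 fold change was the fold change over the square root of F. Log2 CPM used a prior count of 2.

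The 44 gene lists held 898 members, of which 895 were found in the table and 828 were tested. Oga was matched through its older symbol and the mitochondrial genes through names without prefix. Of the 868 genes in any list, 29 were in more than 1 list. Reads of ribosomal protein genes, Gapdh, mitochondrial transcripts and the Mup and Cyp families can be shared with pseudogenes or near-identical copies. A list's score was the mean log2 CPM of its tested members in a library. List differences are differences of mean scores, while log2 fold changes of genes, their signs and their medians are edgeR's fitted values. These are unlike measures and can part where libraries of a group differ widely. Xist, for example, had a fitted 1.85 with mean log2 CPM of 4.02 in KO and 0.05 in WT. KO and WT scores were compared by an exact two-sided permutation test over 792 regroupings, with Benjamini-Hochberg adjustment over the lists. The smallest p that it can give is 0.00126, and the smallest within the 90 regroupings inside Xist classes is 0.0111. Within the shallower and deeper libraries the 35 and 10 regroupings allow no p under 0.0286 and 0.1, so only differences are given there.

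The named genes follow a rule fixed with the lists and the tests before the data were examined. It takes Pck1, then the 12 genes with the largest change per direction past the threshold or, where fewer than 10 pass, the 10 genes with the smallest p, then up to 4 members of each list with the smallest p, and Pck2, S100a11, Cdkn1a, Afp, Glul and Xist. Of the genes the rule allows, the text names a part, and the values of 2 list members that enter the counts are not reported here.

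Alternatives fixed before the data were examined were other scalings (RLE size factors, upper quartile), DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), no filter, a filter of at least 1 CPM in 5 libraries, fits without robust estimation, the number range in the sample titles as a covariate, glmTreat with a fold of 1.5, each library left out in turn and, for lists, a prior count of 0.5, members scaled to unit SD, permutation within title number ranges, camera and fry. Alternatives added after seeing the data were voom without weights, the Xist class (above or under 10 CPM) and the depth class (the deeper against the shallower libraries) as covariates, subsets of libraries by these classes, and leaving out both libraries whose Pck1 levels overlapped.

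The fits were tested on simulated data made from the real means, library sizes and dispersions for the comparison of KO with WT, with 200 of 14421 genes changed. The changed genes were drawn from those with an average log2 CPM over 1, so recovery of genes with lower counts was not tested. edgeR recovered 43 of 50 genes raised 4-fold, 41 of 50 lowered 4-fold, 17 of 50 raised 2-fold and 15 of 50 lowered 2-fold, with 6 unchanged genes called. DESeq2 recovered 45, 45, 25 and 24 with 33 unchanged genes called, and limma-voom with weights 43, 42, 15 and 14 with 5. Each gene was drawn on its own, without variation shared by the genes of a library. The counts of unchanged genes called therefore do not carry over to the real data. There, other splits of the samples gave up to 3550 limma-voom and 814 DESeq2 calls. A planted list of 20 genes lowered by 1 log2 unit came out at −0.90 with an exact permutation p = 0.00253. Its adjusted p of 0.1035 did not pass 0.05. Of 40 unchanged lists, 1 had a p under 0.05 and 0 passed after adjustment. The planted members were drawn independently, while camera estimated a correlation of 0.44 in the real periportal list. A list lowered by that much can thus miss the threshold here.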

Results

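RNA sequencing read counts were collected from hepatocellular carcinomas that diethylnitrosamine had induced in the livers of mice. Diethylnitrosamine is a chemical carcinogen that hepatocytes convert into a DNA-alkylating agent. Of the 12 libraries, 7 came from Pck1-null mice (KO) and 5 from wild-type mice (WT). Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase, which turns oxaloacetate into phosphoenolpyruvate on the path to glucose. The comparison asked how the tumour transcriptome differed between the genotypes. The total count lay between 17462102 and 23663506 in 7 libraries (4 KO and 3 WT), called the shallower libraries here, and between 43071365 and 46747125 in the other 5 (3 KO and 2 WT), called the deeper libraries. Xist, the RNA of the inactive X chromosome, reached 86.6 to 169 CPM (the count scaled to a common library size) in KO replicates 1, 2, 3, 5 and 6 and in WT replicate 4, where the 4 Y-linked genes summed to at most 5 counts. The other 6 libraries held at most 0.573 CPM of Xist and 1463 to 5901 Y-linked counts. The Xist-high libraries were therefore 5 of 7 in KO and 1 of 5 in WT, and the labels state no sex.

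Pck1, located on chromosome 2 from 173153073 to 173159274 (GRCm38.p6), was lower in the KO libraries. Its level was 8.18 ± 1.25 log2 CPM in KO (SD, n = 7) and 11.64 ± 1.16 in WT (SD, n = 5). The fitted difference was −3.28 ± 0.67 on the log2 scale (SE), a 9.69-fold lower level, and the exact two-sided permutation test of the mean log2 CPM gave p = 0.00379. Pck1 counts remained in every KO library, from 111 CPM in KO replicate 4 to 1167 CPM in KO replicate 3, against 1063 to 5822 CPM in WT. The labels do not describe the targeted allele, so whether these counts come from its remaining exons or from cells without the deletion is not known. KO replicate 3 thus lay above WT replicate 4, and the other 6 KO libraries lay below all WT libraries. After adjustment over all genes tested, edgeR's quasi-likelihood test gave an adjusted p = 0.170 for Pck1, DESeq2 gave 0.000173, and the other alternatives 0.0103 to 0.409. Within the shallower libraries the difference was −2.30, and within the deeper ones −4.88.

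**Figure D1:**
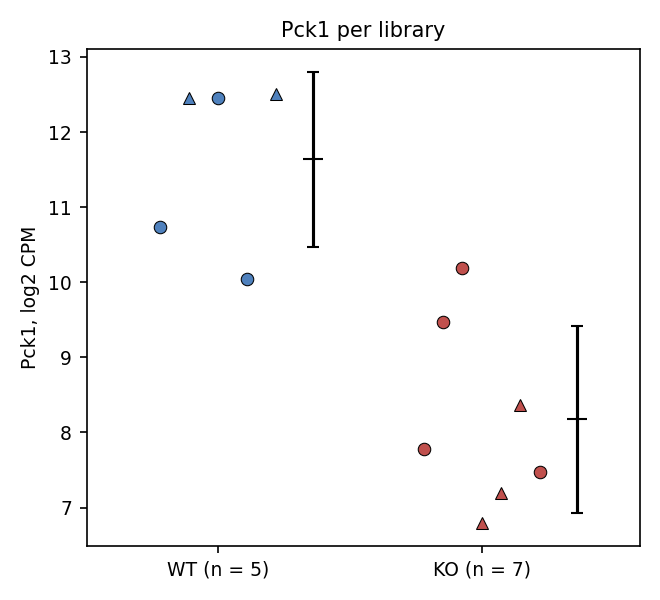
Pck1 in log2 CPM (vertical axis) in each WT and KO library, with circles for the shallower and triangles for the deeper libraries and a black mark and bar for each group's mean and SD. The 7 KO libraries lie between 6.79 and 10.19 and the 5 WT libraries between 10.05 and 12.51, with an overlap of KO replicate 3 and WT replicate 4.

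Across the transcriptome, the 10 genes with the smallest p held 6 that were lower and 4 that were higher in KO. Hsd11b1, which regenerates active glucocorticoid in hepatocytes, was 2.65-fold lower in KO (log2 −1.40 ± 0.20 SE), and Mfsd4b1, a transporter gene, was 3.11-fold lower (−1.64 ± 0.21). Slc30a10, a manganese exporter, differed by −1.73 ± 0.27, Ddo, which oxidises D-aspartate, by −1.16 ± 0.20, and Ceacam1, an adhesion receptor that promotes insulin clearance, by −1.05 ± 0.19. Eci2, an isomerase of unsaturated fatty acid oxidation, was 2.26-fold higher (1.18 ± 0.18), and Gars, the glycyl-tRNA synthetase, was 2.60-fold higher (1.38 ± 0.25). Adamtsl4 differed by 1.90 ± 0.31, Smyd4 by 1.26 ± 0.23 and Pdrg1 by −0.80 ± 0.15. For 9 of these 10 genes all 7 KO libraries lay beyond all 5 WT libraries, and for Gars 6 of 7 did. The genes were chosen by their p in this same comparison, so this separation is no further support for a difference. In the shallower and deeper libraries Slc30a10 differed by −2.26 and −0.74 and Ddo by −0.83 and −1.67.

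None of the 10 genes passed the threshold of an adjusted p under 0.05 in edgeR's quasi-likelihood test (adjusted p from 0.0516 for Mfsd4b1 to 0.170). Over 14666 genes tested, 0 were higher and 0 lower at that threshold. At an unadjusted p under 0.05 there were 1064 higher and 1091 lower genes, against 733 expected by chance. Over other splits of the samples this count had a median of 647 and reached 3796. DESeq2 called 259 higher and 242 lower, and limma-voom with sample weights 938 higher and 1200 lower, with 363 genes called by both. Limma-voom without sample weights called 1 higher and 4 lower. Without KO replicate 6, edgeR called 14 higher and 51 lower genes, among them all 10 named above. The groups did not overlap in 178 genes, or 93 higher and 85 lower in KO, where the mean over regroupings of the libraries is 37.0. Genes vary together and the spread of this count over regroupings was not computed, so chance is not excluded for it. Within the shallower libraries 0 genes passed, with 744 higher and 852 lower at an unadjusted p under 0.05, and within the deeper ones 0 higher and 2 lower passed, with 981 and 1193. With the Xist class as a covariate 0 genes passed, and 785 higher and 907 lower had an unadjusted p under 0.05. The 2 genes that passed within the deeper libraries were Pappa2 and Ren1, and the 5 of limma-voom without weights were Eci2, Ddo, Hsd11b1, Mfsd4b1 and Mup11, of which Pappa2, Ren1 and Mup11 were named after their values were seen.

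**Figure D2:**
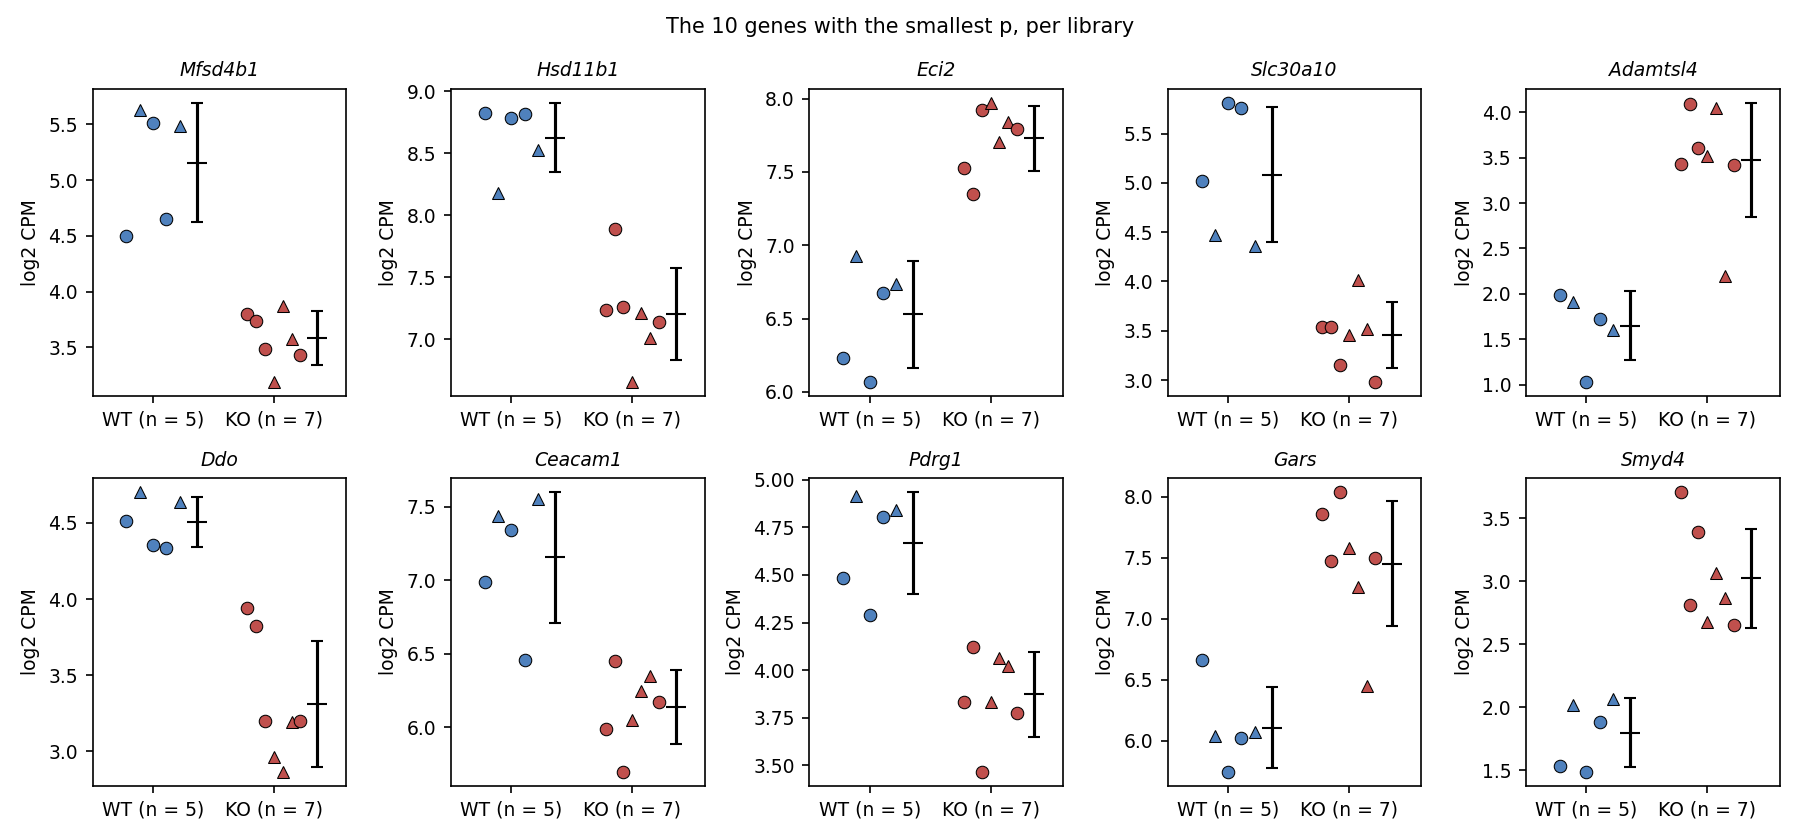
Log2 CPM (vertical axes) of the 10 genes with the smallest p in each WT and KO library, with circles for the shallower and triangles for the deeper libraries and black marks with bars for group means and SD. Hsd11b1 lies between 6.65 and 7.89 in KO and between 8.18 and 8.83 in WT, and Eci2 between 7.35 and 7.97 in KO and between 6.07 and 6.93 in WT.

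Gene lists fixed before the data were examined were compared by their mean log2 CPM per library, with an exact two-sided permutation test over 792 regroupings. Of 44 lists, 0 passed an adjusted p under 0.05, and 8 had an unadjusted p under 0.05, 6 of them lower in KO and 2 higher. With 1 library left out that count of 8 ran from 2 (without WT replicate 2) to 13 (without KO replicate 6). The smallest adjusted p that 1 list alone can reach here is 0.0556, so a pass needs at least 2 lists with a small p. Camera called 17 lists with a preset correlation of 0.01 and 0 with an estimated correlation, and fry called 0. Without KO replicate 6 the lists of periportal and of male-biased genes passed (exact permutation, adjusted p = 0.0476 for each). In both lists KO replicate 6 was the only KO library that did not lie below all WT libraries. Leaving it out thus gave each list the smallest p that the permutation allows. Over the other permutation alternatives the adjusted p of these lists lay between 0.126 and 0.677. Camera's adjusted p for the periportal and the male-biased list was 5.26e-08 and 0.000552 with the preset correlation and 0.610 for each with an estimated correlation. When p was adjusted over the list alone, 39 members in 10 lists passed, against 0 over all genes tested.

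Lists of hepatocyte zone and amino acid metabolism had lower mean scores in KO, and none passed after adjustment. Periportal hepatocyte genes, which mark the hepatocytes around the portal vein, scored 6.73 ± 1.79 in KO (SD, n = 7) and 9.26 ± 0.72 in WT (SD, n = 5), a difference of −2.52 (exact p = 0.0126, adjusted p = 0.243), and 6 of 7 KO libraries lay below all WT libraries. Of the 18 periportal genes measured, 17 had a negative log2 fold change, and adjusted over the list alone 1 passed, Uox, the urate oxidase, at −1.19 ± 0.32 (SE). Cyp2f2 differed by −3.79 ± 1.22 and Igf1, the liver's growth factor output, by −2.05 ± 0.73. The urea cycle and amino acid breakdown list differed by −1.19 (exact p = 0.0316, adjusted p = 0.243, with 5 of 7 KO libraries below all WT libraries), with 21 of 24 members negative, among them Kmo of tryptophan breakdown (−1.16 ± 0.31), Uroc1 of histidine breakdown (−1.49 ± 0.55) and Otc of the urea cycle (−1.08 ± 0.40). Within the shallower and the deeper libraries the periportal difference was −3.11 and −1.93, that of Cyp2f2 −6.06 and −2.68, that of Kmo −0.70 and −1.66, and the urea cycle difference −0.92 and −1.64. With permutation within Xist classes the periportal difference was −2.14 (exact p = 0.0333) and that of the urea cycle list −0.89 (exact p = 0.144). The list of mature hepatocyte genes differed by −0.35 (exact p = 0.104), with 2 of 26 members past the threshold adjusted over the list alone, among them the clotting factor F9 (−0.44 ± 0.12 SE).

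Genes of serine, glycine and methionine metabolism held members with positive and with negative values. The serine and glycine list had a mean difference of 0.32 (exact p = 0.0328, adjusted p = 0.243), with 7 of 7 KO libraries above the WT mean, while its median log2 fold change was −0.04. Adjusted over the list alone, 3 of its 16 members passed, namely Psat1, a step of serine synthesis (2.76 ± 0.85 SE), and Slc1a5, a glutamine and neutral amino acid carrier (2.13 ± 0.56), both higher, and Shmt1, the cytosolic serine hydroxymethyltransferase, lower (−0.72 ± 0.23). The list of the methionine cycle and methyl transfer differed by −0.67 (exact p = 0.0442, adjusted p = 0.243), with 6 of 7 KO libraries below the WT mean, and 5 of its 19 members passed adjusted over the list alone. Among these, lower were Bhmt, which passes a methyl group from betaine to homocysteine (−1.66 ± 0.55), its paralog Bhmt2 (−0.67 ± 0.22) and Dmgdh (−1.02 ± 0.32), and higher was Mat2b (0.34 ± 0.09), a regulatory subunit of methionine adenosyltransferase. Bhmt2 was named after its value was seen. Within the shallower and deeper libraries Slc1a5 differed by 2.82 and 0.55, Psat1 by 2.02 and 3.99, and Shmt1 by −0.40 and −1.12. In the same order, Bhmt differed by −2.55 and −0.97 and Dmgdh by −0.46 and −1.66. The serine and glycine list differed by 0.36 and 0.24, and the methionine list by −0.38 and −1.12. With permutation within Xist classes the methionine list differed by −0.73 (exact p = 0.100).

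In the path to glucose itself, the gluconeogenesis list differed by −0.67 (exact p = 0.116), and within the shallower and deeper libraries by −0.46 and −1.02. Fbp1, the fructose-bisphosphatase of the path, was at −1.38 ± 0.56 (SE), and Pck2, the mitochondrial counterpart of Pck1, at 1.10 ± 0.32, with adjusted p = 0.295 and 0.211 in edgeR's test. Pck2 lay above the WT mean in 7 of 7 KO libraries and above all WT libraries in 3, and differed by 0.74 in the shallower and 1.55 in the deeper libraries. Pdk4, a kinase that shuts pyruvate dehydrogenase, had 1.87 ± 0.67. The lists of glycolysis (−0.23, exact p = 0.474), the pentose phosphate pathway (−0.25, exact p = 0.0732) and the tricarboxylic acid cycle (−0.17, exact p = 0.511) had a p over 0.05, and the last of these had 0.23 in the shallower and −0.77 in the deeper libraries. Oxidative phosphorylation subunits differed by −0.50 (exact p = 0.0518) with 26 of 26 members negative, and Ndufb3 (−0.62 ± 0.15) passed adjusted over the list alone. Mitochondrially encoded transcripts differed by −0.78 (exact p = 0.0934) with 13 of 13 members negative, and by −1.09 with permutation within Xist classes (exact p = 0.0444). In the shallower and deeper libraries the oxidative phosphorylation list differed by −0.19 and −0.97, the mitochondrially encoded list by −0.36 and −1.36, glycolysis by −0.13 and −0.36, and the pentose phosphate pathway by −0.19 and −0.34.

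Lipid genes were led, by p and not by size of change, by Acly, the enzyme that supplies cytosolic acetyl-CoA, at −1.10 ± 0.23 (SE). Acly and Agpat2 of glycerolipid synthesis, at −0.94 ± 0.25, were the 2 of 25 members of the fatty acid synthesis and lipid storage list that passed adjusted over the list alone. That list differed by −0.50 (exact p = 0.124), by −0.80 with permutation within Xist classes (exact p = 0.0444, adjusted p = 0.326), and by −0.43 and −0.72 in the shallower and deeper libraries. WT replicate 4, the only Xist-high WT library, scored 7.41, against 5.84 to 6.46 in the other WT libraries and 5.26 to 6.49 in KO. The differences over all libraries and within Xist classes lean on it, while the deeper libraries do not hold it. The lists of cholesterol synthesis (0.44, exact p = 0.241), fatty acid oxidation and ketogenesis (0.12, exact p = 0.720) and bile acid synthesis and transport (−0.28, exact p = 0.284) differed by less than the threshold. In the shallower and deeper libraries the bile acid list had 0.18 and −0.94, cholesterol synthesis 0.13 and 0.89, and fatty acid oxidation 0.29 and −0.0875.

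Interferon response genes had a list difference of −0.79 (exact p = 0.0404, adjusted p = 0.243), with 5 of 7 KO libraries below all WT libraries. Adjusted over the list alone, 10 of the 27 members passed and all 10 were lower, among them the antiviral genes Oasl1 (−2.37 ± 0.55 SE), Isg15 (−1.91 ± 0.47) and Ifit3 (−1.80 ± 0.44) and the RNA sensor Ifih1 (−0.66 ± 0.16). The list differed by −0.33 in the shallower and −1.50 in the deeper libraries, Isg15 by −0.60 and −2.84, and Ifih1 by −0.40 and −0.99. The list differed by −0.60 with permutation within Xist classes (exact p = 0.167). Neutrophil genes had a list difference of 1.28 (exact p = 0.130), and 10 of 15 members passed adjusted over the list alone, all 10 higher, with Mpo at 3.99 ± 1.24, Elane at 3.91 ± 1.23, Camp at 3.86 ± 1.32, Mmp8 at 3.51 ± 1.07, S100a8 at 3.26 ± 1.12 and S100a9 at 3.03 ± 1.04. Their high levels lay in 3 KO libraries, with neutrophil scores of 6.11 in replicate 3, 4.86 in replicate 6 and 4.22 in replicate 4, while the other 4 KO libraries scored 1.92 to 2.24 and WT 1.49 to 2.44. The erythroid list (0.33, exact p = 0.693) was also highest in KO replicate 3, at 6.03. The difference of the neutrophil list was 0.87 in the shallower and 1.72 in the deeper libraries.

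Among markers of other cell types, endothelial genes differed by −0.81 (exact p = 0.0556), and by −0.91 and −0.70 in the shallower and deeper libraries, with Kdr, the vascular growth factor receptor, at −1.02 ± 0.29 (SE) and the sinusoidal lectin Clec4g at −2.15 ± 0.79. The list of Kupffer cells and macrophages differed by −0.72 (exact p = 0.157), with the Kupffer cell lectin Clec4f at −2.47 ± 0.87. The other such lists were T and NK cells (0.38, exact p = 0.385), B and plasma cells (−0.57, exact p = 0.231), MHC class II presentation (0.31, exact p = 0.721), extracellular matrix and stellate cells (−0.15, exact p = 0.668), cholangiocytes (−0.20, exact p = 0.780) and adipose, pancreas and muscle (0.39, exact p = 0.141). The median of the fitted log2 fold changes of the cholangiocyte members was positive, at 0.23, while the difference of the list score, another measure, was negative. In the shallower and deeper libraries the Kupffer cell list differed by −0.95 and −0.44, and T and NK cells by 0.82 and −0.31. In the same order extracellular matrix differed by −0.49 and 0.31, cholangiocytes by −0.85 and 0.60, and MHC class II by 0.31 and 0.56.

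In the tumour-related lists the libraries differed within KO. All 22 beta-catenin liver targets had a positive fold change, the list differed by 1.40 (exact p = 0.274), and 2 members passed adjusted over the list alone, Tnfrsf19 (2.80 ± 0.75 SE) and the Wnt feedback gene Znrf3 (3.03-fold higher, SE 0.45 on the log2 scale). KO replicates 1, 2 and 3 had the highest list scores, 8.40, 6.78 and 7.89, and KO replicate 5 the lowest, 1.32, so that the difference was 3.09 in the shallower and −0.92 in the deeper libraries. Glul, the glutamine synthetase that beta-catenin drives, was at 13.20 to 13.96 log2 CPM in those 3 libraries and at 4.99 in KO replicate 5, with a group difference of 2.75 ± 1.38, or 3.15 in the shallower and −0.50 in the deeper libraries, where Znrf3 had 1.98 and 0.74. All 38 cell cycle genes had a positive fold change, with a list difference of 0.56 (exact p = 0.256), 0.97 in the shallower and −0.08 in the deeper libraries. The hepatocellular carcinoma and oncofetal list differed by 0.49 (exact p = 0.224), with Bex1 at 2.62 ± 0.78 and the fetal serum protein Afp at 1.03 ± 1.29, which ranged from 2.87 to 10.48 log2 CPM in KO and from 2.85 to 9.76 in WT. In the p53 target list (0.12, exact p = 0.631), 3 of 20 members passed adjusted over the list alone, Bax (0.58 ± 0.18) and Sesn1 (0.84 ± 0.26) higher and Fas (−0.71 ± 0.17) lower, while Cdkn1a had 0.07 ± 0.40. In the shallower and deeper libraries the oncofetal list differed by 0.23 and 0.84, Afp by 0.99 and 2.62. Fas differed by −0.50 and −1.01, Cdkn1a by −0.16 and 0.56 and the p53 target list by −0.0668 and 0.40.

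**Figure D3:**
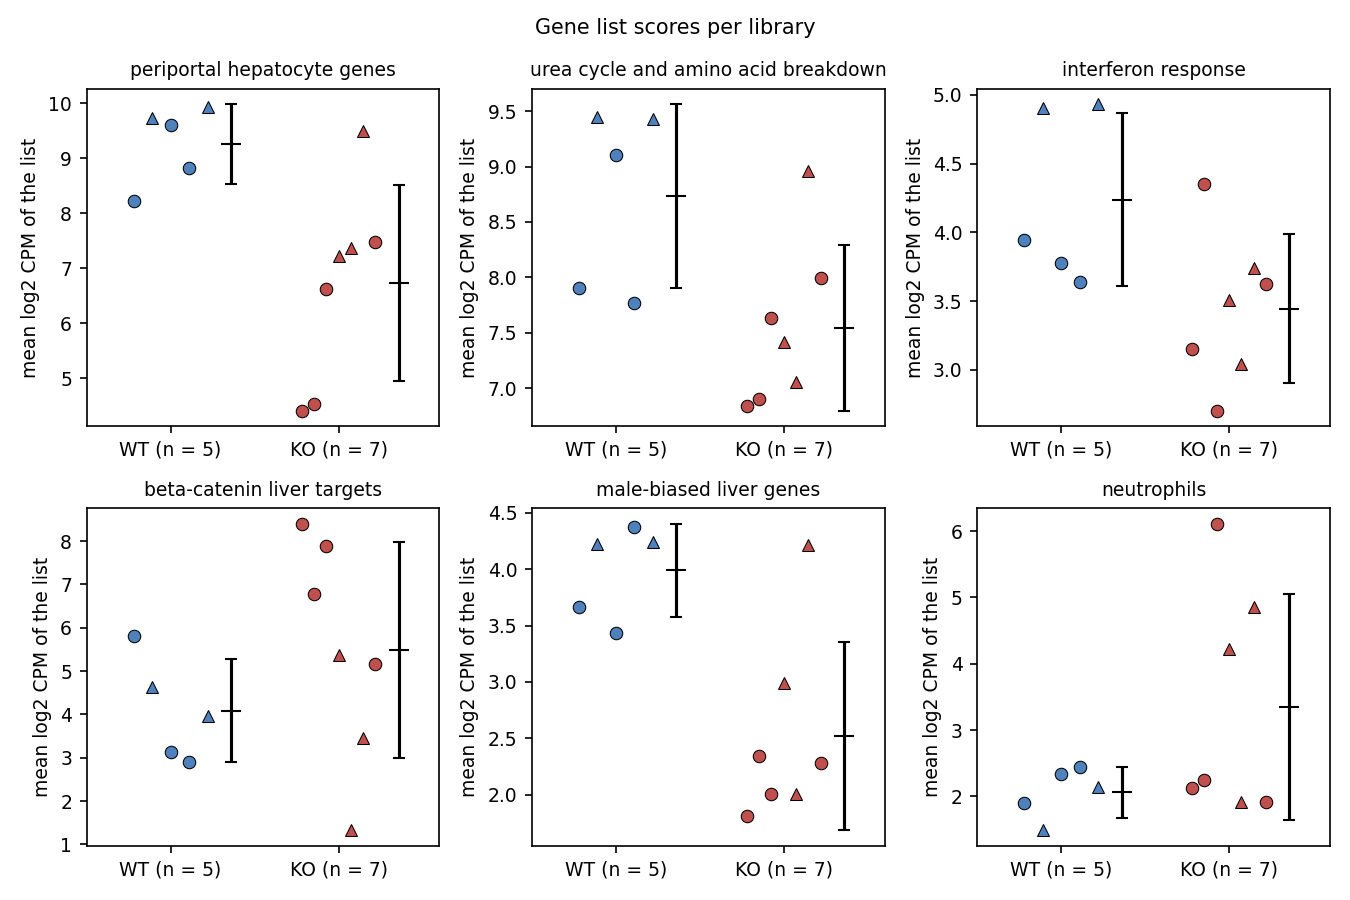
Mean log2 CPM of the members of 6 gene lists (vertical axes) in each WT and KO library, with circles for the shallower and triangles for the deeper libraries and black marks with bars for group means and SD. KO replicate 6, the KO triangle at 9.50 in the periportal panel, lies within the WT range of 8.21 to 9.93, and the neutrophil scores above 4 belong to KO replicates 3, 4 and 6.

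Both lists of liver genes that differ between the sexes had lower mean scores in KO. The male-biased list differed by −1.47 (exact p = 0.00884, adjusted p = 0.243), with 6 of 7 KO libraries below all WT libraries and Mup3, a major urinary protein, at −3.70 ± 1.13 (SE), and the female-biased list by −1.68 (exact p = 0.0391, adjusted p = 0.243), with 4 of 7 below all WT libraries, Cyp3a44 at −3.28 ± 0.92 and Cyp17a1 at −2.94 ± 0.87. Within the shallower and deeper libraries the male-biased difference was −1.62 and −1.25, the female-biased one −1.46 and −1.97, that of Mup3 −5.52 and −0.75, and that of Cyp3a44 −4.55 and −2.20. With permutation within Xist classes these were −1.51 (exact p = 0.0111, the smallest p that permutation can give) and −1.84 (exact p = 0.0667). The Y-linked list differed by −3.90 (exact p = 0.212) and Xist by 1.85 ± 1.87. Reads of Mup3, Cyp3a44, Ifit3 and Mfsd4b1 can be shared with near-identical family members, so their values are uncertain.

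Cytosolic ribosomal protein genes had a list difference of 0.30 (exact p = 0.0429, adjusted p = 0.243), with 7 of 7 KO libraries above the WT mean and 31 of 31 members positive, for example Rpl3 at 0.52 ± 0.14 (SE) and Rplp0 at 0.58 ± 0.20. The difference was 0.40 in the shallower and 0.18 in the deeper libraries, with Rplp0 at 0.75 and 0.30, and reads of these genes can be shared with processed pseudogenes. The S100 family list differed by 0.37 (exact p = 0.338), with S100a11 at 0.75 ± 0.43, and the list of H3K9 methylation enzymes and readers by 0.06 (exact p = 0.610), with Trim28 at 0.40 ± 0.15. Of the remaining lists, hexosamine and O-GlcNAc genes differed by 0.01 (exact p = 0.939), cytochrome P450 drug metabolism by −0.45 (exact p = 0.592; median log2 fold change 0.09), NRF2 targets by −0.25 (exact p = 0.538), the unfolded protein and integrated stress response by 0.16 (exact p = 0.313; median −0.07), and MAPK and PI3K feedback genes by 0.23 (exact p = 0.244). The acute phase response differed by −0.48 (exact p = 0.226), circadian clock genes by 0.09 (exact p = 0.590), and immediate early and heat shock genes by 0.15 (exact p = 0.634). The P450 list had 0.50 in the shallower and −1.78 in the deeper libraries, and the NRF2 list 0.37 and −1.13. In the same order the S100 list had 0.51 and 0.10, S100a11 0.0805 and 1.68, the MAPK and PI3K list 0.0141 and 0.52, and the acute phase list −0.60 and −0.32.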

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

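The tests of exchanged labels, Xist classes, hepatocyte share and beta-catenin were chosen after the results were seen, and the counts over other splits of the samples before.

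Among 113 values that the text reports or draws on per library, 15 had a library far from the others of its group, by the gap to its neighbour as a share of the group's range. Chance gives about 1 in 20 groups, or 11.3 over the 226 groups examined. KO replicate 6 stood apart in Adamtsl4 (0.645) and Tnfrsf19 (0.643), below the other KO libraries, and above them in Fbp1 (0.674), Oasl1 (0.686) and the acute phase list (0.574). KO replicate 5 lay below the other KO libraries in Uox (0.593), Pdk4 (0.585) and the P450 list (0.585), and above them in the list of H3K9 methylation enzymes (0.589). KO replicate 1 was above in the list of the unfolded protein and integrated stress response (0.638). Among WT, replicate 1 was above in Pck2 (0.75), replicate 2 below in Elane (0.723), replicate 3 below in the NRF2 list (0.731), and replicate 4 above in Xist (0.724) and below in the Y-linked list (0.92).

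The number of genes that differed hung on a few libraries. Of 100 splits of the 12 samples into groups of 7 and 5, all 100 gave at least the real count of 0 edgeR calls, as any split must, so that this test is void (highest other 1053), and 3 gave at least the real 2155 genes at an unadjusted p under 0.05 (highest other 3796). For limma-voom with sample weights 3 of 100 splits reached the real 2138 calls (highest other 3550), and for DESeq2 3 of 50 reached the real 501 (highest other 814). By the rule set before, a share under 0.05, the count at an unadjusted p and that of limma-voom passed, and that of DESeq2 did not. The real split is among the 3 each time, so the verdicts differ only by the number of splits drawn. These draws are too few to place the shares firmly on either side of 0.05, and chance is not excluded. The split with 1053 edgeR calls exchanged KO replicate 6 and WT replicate 1, which points to a structure of the samples that the genotype labels do not give, and the closest library to KO replicate 6 was WT replicate 2 (Spearman 0.968 across genes). Exchanged labels do not account for it by Pck1, since KO replicate 6 had 329 CPM, below the 1063 CPM of the lowest other WT library, and WT replicate 1 had 1696 CPM, above the 1167 CPM of the highest other KO library. The share of tumour in each library and the stage of the tumours are not in the labels and stay open.

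The periportal list was lower by −2.52 in KO. Within Xist classes −2.14 remained (exact permutation p = 0.0333, adjusted p = 0.326). This argues against the unequal number of Xist-high libraries as the sole reason. It does not rule that number out, since the list did not pass after adjustment and WT replicate 4 was the only Xist-high WT library. A smaller share of hepatocytes does not account for all of the difference, since the mature hepatocyte list differed by −0.35 (SD within groups 0.36). Beta-catenin activity, which holds down periportal genes in normal liver, may be part of the pattern: over the 7 KO libraries the scores had Pearson r = −0.69 (exact permutation p = 0.0800) and Spearman rho = −0.86 (exact permutation p = 0.0238), 1 relation being computed. Without KO replicates 1 and 5, those farthest from the median, r was −0.78 (exact permutation p = 0.108), and 5 libraries are too few for a firm test. With the beta-catenin score as a covariate the periportal difference was −1.88. Of the 7 KO libraries, 6 lay below all WT libraries in the periportal list, while 3 lay above all WT libraries in the beta-catenin list. KO replicate 5, with the lowest beta-catenin score, was among those 6. In the deeper libraries the beta-catenin list differed by −0.92 and the periportal list by −1.93. These values argue against higher beta-catenin activity as the sole reason, and as a part of the pattern it stays open. Beside it stays a biological effect of Pck1 loss, which was not tested apart from the groups. The share and stage of tumour, which the labels do not give, also stay open.

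The male-biased and female-biased lists were both lower in KO. An excess of female mice among KO would by itself raise the female-biased list, and that list differed by −1.68 (exact p = 0.0391, adjusted p = 0.243). This argues against such an excess as the sole reason but does not rule it out, since the list did not pass after adjustment. A smaller share of hepatocytes would lower the mature hepatocyte list by a like amount, and that list differed by −0.35 against −1.47 for the male-biased list. A genotype effect was not tested apart from the groups. It stays open beside the age of the mice and the share and stage of tumour, which the labels do not give.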

How the results depend on the processing

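Alternatives with the Xist or depth class as covariates, subsets of libraries by these classes, voom without weights and both overlapping libraries left out were chosen after seeing the data. Pck1 was lower in KO in every alternative, from −5.01 (Xist-low libraries) to −2.30 (shallower libraries). It passed the threshold with DESeq2 (−3.28, adjusted p = 0.000173) and limma-voom with sample weights (−3.87, adjusted p = 0.0103), and its adjusted p was 0.0564 to 0.409 elsewhere. Leaving out 1 library gave 0 to 14 genes higher and 0 to 51 lower, with the highest counts without KO replicate 6 and otherwise 1 gene at most (Hsd11b1 without KO replicate 2, Mfsd4b1 without WT replicate 1 or 4), and 0 to 2 lists. DESeq2 gave 259 higher and 242 lower genes (1628 higher at an unadjusted p under 0.05), limma-voom with sample weights 938 and 1200 (2407 and 2460), limma-voom without sample weights 1 and 4, upper quartile scaling 1 lower, no filter 1 lower (1665 at an unadjusted p), the stricter filter 1 lower (Mfsd4b1 in all 3), title number range 2 lower (Mfsd4b1 and Ddo), depth class as a covariate 1 higher (Eci2) and 2 lower (Hsd11b1 and Mfsd4b1), the deeper libraries 2 lower, and the Xist-low libraries 17 and 17. The filter left 14666 of the 26342 genes with any count, and how far depth sets this number was not tested. Camera with a preset correlation gave 17 lists. The cause of these moves was not tested, except that subsets hold fewer libraries. Of the named genes' other values, 960 of 1076 kept direction and did not pass the threshold over settings, while 109 passed it and 7 reversed. With a library left out these were 783 of 805, with 18 that passed and 4 reversed. For the lists they were 459 of 484 (0 and 25) and 509 of 528 (2 and 17). None of these genes or lists passed in the main fit, so the kept values show a kept direction and not a difference that was found again.

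The cause of the reversals was not tested. With the Xist class as a covariate these were Xist (−0.95) and the lists of hexosamine genes (−0.0558), fatty acid oxidation (−0.14), cholangiocytes (0.29) and Y-linked genes (0.18). With depth and Xist class together the same 5 had −0.66, −0.0322, −0.0860, 0.12 and 0.14. In the shallower libraries Cdkn1a had −0.16 and the lists of the tricarboxylic acid cycle 0.23, H3K9 methylation −0.0163, hexosamine genes −0.0794, bile acids 0.18, P450 0.50, NRF2 0.37 and p53 targets −0.0668. In the deeper libraries Glul had −0.50 and the lists of fatty acid oxidation −0.0875, cell cycle −0.0765, beta-catenin targets −0.92, extracellular matrix 0.31, cholangiocytes 0.60 and T and NK cells −0.31. In the Xist-low libraries Glul had −0.90, Afp −0.66, Xist −2.93, extracellular matrix 0.0203, cholangiocytes 1.41 and Y-linked genes 0.12. Cholangiocytes had 0.0905 with both overlapping libraries left out. Over the libraries left out in turn, the range was −0.0414 to 0.0697 for hexosamine genes, −0.0582 to 0.30 for fatty acid oxidation, −0.11 to 0.54 for Cdkn1a, −0.61 to 0.21 for cholangiocytes, −0.0697 to 0.83 for MHC class II, −0.0769 to 0.84 for erythroid cells, −0.69 to 0.00761 for P450, −0.42 to 0.0240 for extracellular matrix, −0.0207 to 0.16 for clock genes, −0.00165 to 0.38 for immediate early genes and −0.35 to 0.00924 for glycolysis.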

Other observations

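Slc4a1, the anion exchanger of red cells, reached 7.02 log2 CPM in KO replicate 3 and 5.69 in KO replicate 4, the libraries that also held high Mpo (6.46 and 3.93), while Slc4a1 was at most 2.21 in WT. KO replicate 6, with Mpo at 4.04, had Slc4a1 at 1.68, within the WT range. In Slc4a1, 3 of 7 KO libraries lay above all WT libraries, so a further library without a high neutrophil score was among them. Nkd1, a Wnt feedback gene, was at 8.80 and 8.48 in KO replicates 1 and 3 and at 0.12 in KO replicate 5, with a group difference of 5.01 in the shallower and 0.22 in the deeper libraries. Psat1 was above 4 log2 CPM in all 7 KO libraries and in WT replicate 1 (5.50), against 1.12 to 3.57 in the other 4 WT libraries. Aldoc, the C isoform of aldolase, had a log2 fold change of 1.06 ± 0.46 (SE), with 5 of 7 KO libraries above all WT libraries and 0.65 and 2.14 in the shallower and deeper libraries. Prlr, the prolactin receptor, had −1.43 ± 0.53, with 6 of 7 below all WT libraries.

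With genotype in the model, 102 genes differed between the depth classes in edgeR's test, 96 of them higher in the shallower libraries. Of the 93 with a RefSeq entry, 54 were pseudogenes. Between the Xist classes 5 genes differed, Xist and the 4 Y-linked genes.

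Whether alleles of another strain around the targeted locus alter neighbours of Pck1 was a test set before the data were examined. The test was set for genes past the threshold, of which there were 0 among the 269 tested genes within 20 Mb of Pck1 and 0 elsewhere, so as planned it is void. At an unadjusted p under 0.05, chosen afterwards, the share was 16.4% (exact 95% binomial interval 12.1 to 21.3%, with genes taken as independent) against 14.6% elsewhere, a ratio of 1.12 (one-sided Fisher's exact test p = 0.238). An excess of 1.5 times at that p lies outside the interval, and an effect on few neighbours stays open.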
